A study of Arabidopsis thaliana with 4 samples.

How the data were processed

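Chromatin from whole roots of Arabidopsis seedlings grown for 5 days without iron was immunoprecipitated with an antibody against GFP. The tagged line carried ProPYE:PYE:GFP in the pye-1 mutant, and wild-type seedlings without GFP gave the background. Per the labels' protocols, DNA from both immunoprecipitations was amplified by PCR and labelled with Cy3 or Cy5. Each array held tagged and wild-type material together. There were 2 biological replicates, each hybridised on 2 arrays with the dyes exchanged, so 4 arrays formed 1 group with n = 2. Input DNA is not listed in the labels.

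Per the file headers, the deposited intensity values came from Agilent Feature Extraction. Its processed signal was the spot signal with background subtracted, spatially detrended and multiplied by 1 linear dye factor per channel, and small signals were replaced by surrogates. The mean and local background signals in the same files are deposited intensities with no correction. Per the file headers, the LogRatio column is the log10 of Cy5 over Cy3. The deposited value table of the series holds a log10 ratio as well: each column equalled the LogRatio of its own array, with the sign turned on the dye-swapped arrays (correlation 1 or -1), so scale and direction are known and no further centring was applied. Each of its 4 columns had a median of 0. The headers name no genome build.

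From these values the log2 ratio of PYE-GFP over wild type was taken from the processed signals, with the direction from the dyes in the labels. Control spots and spots flagged as outliers by the scanner software were dropped, spots of a probe were averaged, and each array was centred on its median, with no loess or quantile step. Dye-swapped arrays of a replicate were averaged before any test. A window was the mean over probes within 500 bp of a probe's centre, with at least 2 probes, which gave 234614 windows. Each array held 243504 spots, of which 237976 carried 237575 probes and 5528 were controls. Of the probe spots, between 90.9% and 96.1% stood well above background in the PYE-GFP channel and between 94.7% and 96.1% in the wild-type channel. The median probe spacing was 158 bp and the median window held 5 probes. The number of arrays limits the precision.

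Windows and genes were tested with limma (lmFit on an intercept, then eBayes, two-sided, Benjamini-Hochberg over all windows or genes, adjusted p under 0.05). With 2 replicates the fit has 1 residual degree of freedom. For windows limma estimated infinite prior degrees of freedom, which gives all windows the same error, and for genes a prior of 8.40. Windows are also described by a size rule without a test: more than 3 robust standard deviations from the median in both replicates. Windows that passed and lay within 500 bp of each other were joined, and 2 joined windows made a region. Chance was described by moving replicate 2 around the genome by 100 random circular shifts. Counts below the median stand beside those above it.

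The array's numbering was compared with the gene list of assembly TAIR10.1, whose coordinates are not printed. Gene positions in the table fitted the array's numbering directly for 48.0% of probes. Of 236 overlapping blocks of 1000000 bp, 102 matched, 110 were displaced by 1100 to 26100 bp, and the others had no settled displacement. Positions were not converted, and genes are named only where the numbering matched, so large parts of chromosomes 1, 2, 3 and 5 have no gene names here. All 102 listed locus tags were looked up, and 54 of these genes had a value. PYE lies in a part that did not match, and its locus, planned as a comparison, was not analysed here. The table gives no strand, so the planned promoter value became a gene-flank value: the mean over probes from 1000 bp outside to 200 bp inside either end of a protein-coding gene, with at least 2 probes. This gave values for 12306 of 27432 genes.

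In all, 10 lists of genes were fixed beforehand, and 9 were tested with limma's camera at a preset correlation of 0.01, the bHLH Ib list having 1 gene with a value. E-box motifs were sought in the tiled probe sequences within 250 bp of each region's peak probe, because no genome sequence was used here. Fisher's exact test compared regions with 10 control probes per region, matched on GC content in 5 bins and on the number of probes, in place of the planned match on promoter position. Named in the text are up to 15 regions with the highest and the 3 with the lowest mean, the 10 gene flanks above and 5 below 0 with the smallest p and both replicates on the same side, and always ZIF1, FRO3, NAS4, PYE, BTS, ILR3, FIT, IRT1, FRO2, bHLH38, bHLH39, FER1 and FER4. The design, this rule, the lists and most alternatives were chosen before the data were examined.

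Each step was tested on simulated data with 200 added sites. They were made from these arrays with a running median over 100000 bp on either side removed and each replicate moved by its own circular shift. Over 234660 windows, limma recovered 6.0% of sites of log2 0.5, 46.3% of sites of log2 1 and 100% of sites of log2 2. Away from added sites it called 62 windows above and 177 below 0. Over 12308 genes, limma recovered 13.4%, 91.0% and 100% of flanks shifted by the same sizes. The region rule recovered 0%, 4.5% and 92.4% of sites, with 2 regions above and 6 below the median that held no added site. Camera called a list of 20 shifted genes and did not call a list of 20 others. A displacement of 5000 bp in the numbering was found as 5000 bp.

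Alternatives were normexp (offset 50) on the mean and background signals, loess, a filter on dim probes (88.95% kept), removal of the GC trend, each dye orientation alone, the deposited value table, all 4 arrays as units with a dye term, robust eBayes with a trend, other window widths, probe minimums, size rules, gene spans, motif distances and controls, and each replicate left out. After the values were seen, fits were added with a running median over 100000 bp on either side removed, with the GC trend and that median removed, without the raised stretches of chromosomes 1 and 4, with the size rule lowered to 2 robust standard deviations after the running median, and with the biological replicate as a random block. Software was R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.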

Results

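PYE (POPEYE) is a basic helix-loop-helix transcription factor of the root's response to iron deficiency. The log2 ratio of PYE-GFP to wild-type DNA after immunoprecipitation was measured on 4 tiling arrays from 2 biological replicates. Each array carried 237575 probes at a median spacing of 158 bp, and the dye-swapped arrays of a replicate gave window values that correlated at 0.909 and 0.855 across windows. Positions are in the array's numbering, whose build is not named.

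Which places of the genome carried more DNA in the PYE-GFP immunoprecipitate was asked over 234614 windows of 500 bp on either side of a probe. The highest region lay on chromosome 3 from 17577781 to 17578947, with a peak of 2.09 ± 0.58 (SD, n = 2) on the log2 scale, or 4.25-fold (limma, adjusted p 1.25e-08). Replicate 1 gave 2.50 and replicate 2 gave 1.67, and no gene was assigned because the numbering there differs from the gene table. The tagged line carries an added PYE construct, and PYE lies in the part of chromosome 3 without gene names. An overlap of this region with PYE was not checked, so an added copy is not separated from binding here. A further region on chromosome 3, from 17789078 to 17789601, had a peak of 1.21 ± 0.12 (SD, n = 2; limma, adjusted p 0.0458) and no assigned gene either. The other 12 of 14 reproducible regions lay within the first 1000000 bp of chromosome 4. The highest of these, at 1.84 ± 0.04 (SD, n = 2; limma, adjusted p 2.23e-06), overlapped AT4G01860, which encodes a WD40-repeat protein. The next, at 1.62 ± 0.30 (SD, n = 2), overlapped SYP42, a syntaxin of the trans-Golgi network, and AT4G02200. A region at KEA2, a potassium exporter of the chloroplast envelope, peaked at 1.45 ± 0.08 (SD, n = 2), and the space between WRKY22, a transcription factor of defence, and AT4G01245 peaked at 1.37 ± 0.001 (SD, n = 2). Peaks between 1.17 and 1.35 lay over AGY1, a protein of chloroplast protein import, over the phospholipase D gene PLDBETA2, over QUA3, a methyltransferase of pectin formation, over EDA8, over AT4G01280 and AT4G01290, AT4G02040 and AT4G02220, and over AT4G01897 with GLB1, a nitrogen sensor. The peak at GLB1 did not pass limma (adjusted p 0.0691).

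Across all windows limma called 98 above and 39 below 0, in 30 and 15 separate places. Of the 98, 67 lay in the chromosome 4 stretch and 9 in the highest region of chromosome 3. In simulated arrays limma also called 62 windows above and 177 below 0 away from any added site, and the size rule passed 2 regions above the median there that held no added site. Those arrays had the running median removed, replicates shifted apart and 200 sites added, so they are no like match for the 98 and 39. After the same removal the measured arrays gave fewer calls, as given below, but the shifts and the added sites still differ. The simulated counts therefore set no rate of chance calls. They do show that limma can call windows without an added site, so single calls carry little weight. The size rule passed 66 windows above the median, against 2.50 for independent lists, and 13 below it, against 1.13. The 14 regions compare with a mean of 0.42 and at most 5 in 100 circular shifts of replicate 2, but for the 2 regions on chromosome 3 alone 6 of the 100 shifts, which included the raised stretches, gave as many, and 1 of 100 once the running median was removed. With all 4 arrays as units and a dye term limma called 0 windows (13475 above and 17284 below 0 at an unadjusted p under 0.05), and the highest peak was 1.12 with normexp signals and 1.37 in windows of 1000 bp. After the running median was removed, limma called 13 windows above and 29 below 0, 2 regions passed the size rule above and 3 below the median, and the 12 peaks of chromosome 4 stood between 0.44 and 1.22.

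**Figure D1:**
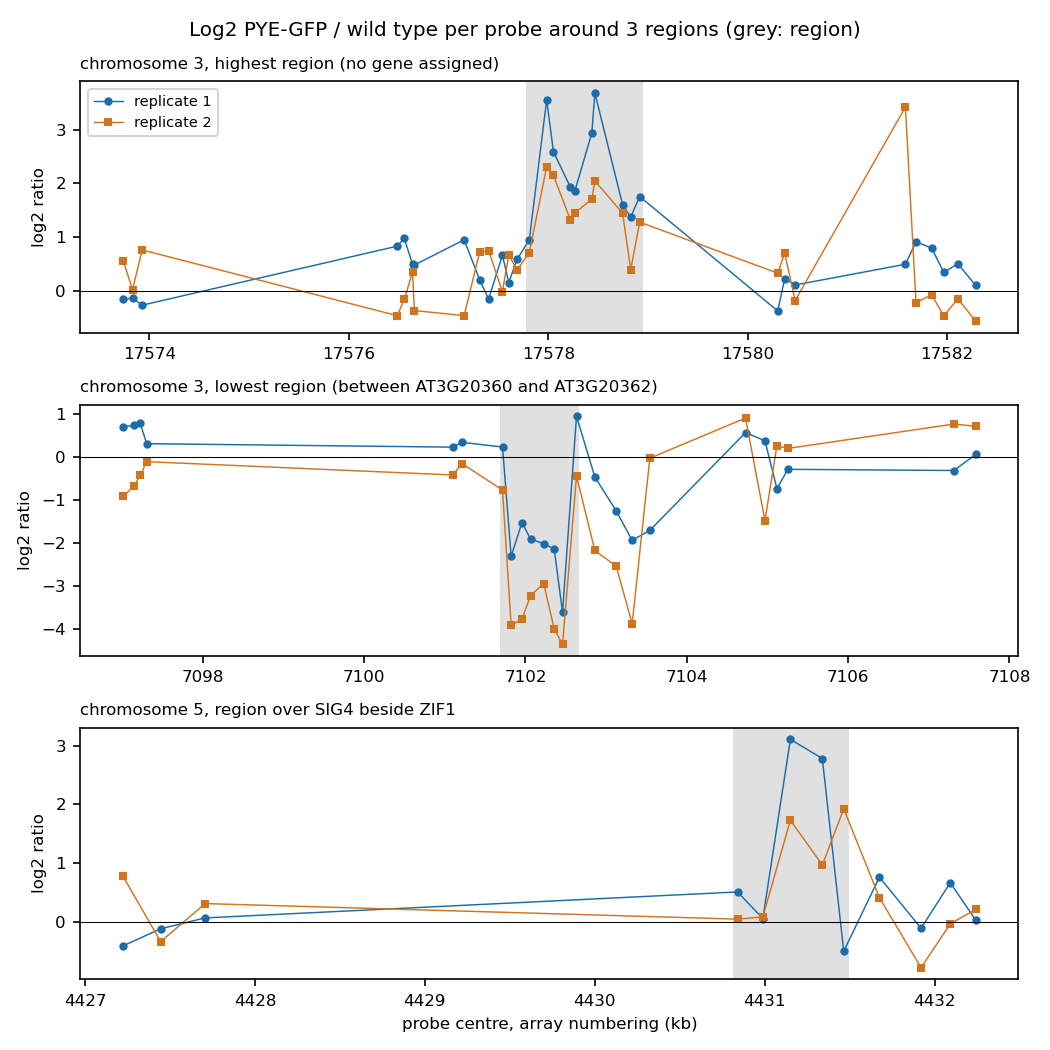
Log2 ratio of PYE-GFP to wild type per probe (vertical axis) against the probe's centre in kb (horizontal axis) for replicate 1 and replicate 2, around the highest region, the lowest region and the region beside ZIF1 (grey). In the highest region the window peaks were 2.50 and 1.67, and in the lowest -1.89 and -3.27.

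Which places carried less DNA in the PYE-GFP immunoprecipitate was the mirror question, since a tagged factor gives few such sites. The lowest region lay on chromosome 3 from 7101687 to 7102663, between AT3G20360 and AT3G20362, at -2.58 ± 0.98 (SD, n = 2; limma, adjusted p 7.04e-14), with -1.89 in replicate 1 and -3.27 in replicate 2. A neighbouring region from 7103294 to 7103572, between the same genes, had -1.89 ± 0.36 (SD, n = 2; limma, adjusted p 9.76e-07). AT3G20360 encodes a TRAF-like protein, and the function of AT3G20362 is not given in the sources used here. The remaining region, on chromosome 5 from 5134248 to 5134531, overlapped AT5G15740, a glycosyltransferase of pectin synthesis, at -1.73 ± 0.12 (SD, n = 2; limma, adjusted p 1.84e-05). Circular shifts gave a mean of 0.24 and at most 2 regions below the median in 100 draws. Once the running median was removed, 3 regions lay below the median, against a mean of 0.39 and at most 2 in the shifts. A single simulated set with the running median removed and no site added below 0 gave 6. That set was 1 draw, with both replicates moved and sites added above 0, so it is no like match. The weight of the count of 3 was thus not settled. The depth of the lowest region was not compared with the shifts. With normexp signals 0 regions passed the size rule below the median, AT5G15740 stood at -0.09 and the pair of regions between AT3G20360 and AT3G20362 at -0.76 and -0.81.

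Regional level along the chromosomes was compared after the values were seen. The first 1000000 bp of chromosome 4, which hold FRI, SYP42 and WRKY22, had a median log2 ratio of 0.74 in replicate 1 and 0.69 in replicate 2 over 2561 probes. The next 1 Mb had 0.10 and -0.03. The first 700000 bp of chromosome 1, which hold the root ferric chelate reductase gene FRO2, had 0.42 and 0.40 over 1586 probes, against 0.08 and 0.00 in the next 1 Mb. In these stretches 437 of 476 genes had flanks higher in both replicates. The stretches were sought as runs of bins with medians above 0.25 in both replicates, so that share was largely built in. The lowest of the 8 array medians was 0.38. With normexp signals the medians were 0.40 for the chromosome 4 stretch and 0.22 for the chromosome 1 stretch, and the lowest array, that of replicate 2 with PYE-GFP in Cy3, had 0.14 and 0.058.

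**Figure D2:**
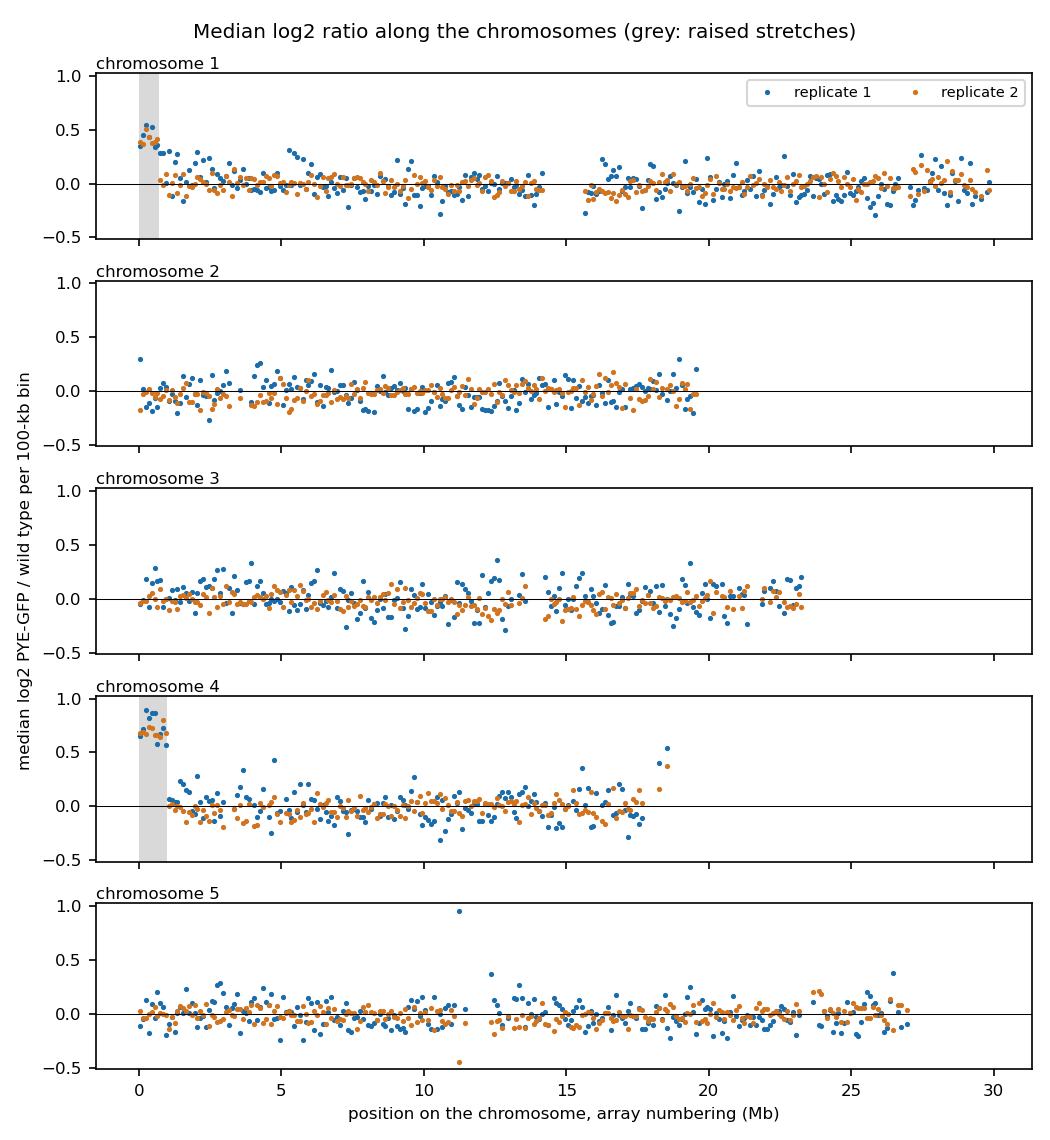
Median log2 ratio of PYE-GFP to wild type in bins of 100 kb (vertical axis) against position in Mb (horizontal axis) on the 5 chromosomes for both replicates, with the raised stretches in grey. The medians of the chromosome 4 stretch were 0.74 and 0.69, and those of the chromosome 1 stretch 0.42 and 0.40.

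Binding beside genes, and the targets for which the study is known, were examined over the flanks of 12306 genes. ZIF1, a vacuolar transporter of the chelator nicotianamine, had a flank value of 0.53 ± 0.13 (SD, n = 2), 1.44-fold, with 0.43 in replicate 1 and 0.62 in replicate 2. It was higher on 4 of 4 arrays and did not pass limma, with an adjusted p of 0.847 over all genes and 0.0528 adjusted over the study's targets and 0.185 over the vacuole and storage genes, and normexp signals gave 0.23 and the narrower span 0.33. The replicates differed by probe and by end of the gene. The end with 6 probes gave 0.61 in replicate 1 and 0.45 in replicate 2. There the probe at 4431316 had 2.78 and 0.97, and its neighbour at 4431436 had -0.50 and 1.92. The end with 4 probes gave 0.18 and 0.87. FRO3, a ferric reductase of mitochondria, had 0.20 ± 0.44 (SD, n = 2), with 0.51 in replicate 1 and -0.12 in replicate 2. The flank of FRO2 stood at 0.41 ± 0.34 (SD, n = 2) within the raised stretch of chromosome 1, and at -0.045 once the running median was removed. IRT1, the main iron importer of the root surface, had -0.21 ± 0.22 (SD, n = 2), BTS, an E3 ligase that limits iron uptake, 0.03 ± 0.30 (SD, n = 2), and the ferritin gene FER1 0.06 ± 0.48 (SD, n = 2), each of which changed sign under an alternative. NAS4, PYE, ILR3, FIT, bHLH38, bHLH39 and FER4 were not analysed here, since they had no value in matching numbering. The 10 leading flanks above 0, namely AT4G02200 (1.62), AT4G02220 (1.52), AT4G01870 (1.44), AT4G02210 (1.14), AT4G01290 (1.14), AT4G01860 (1.13), SYP42 (1.12), AT4G01245 (1.09), AT4G01790 (1.07) and AT4G00895 (1.07), all lay in the chromosome 4 stretch. The 5 leading flanks below 0 were AT3G20360 (-2.23 ± 0.98), AT3G20362 (-1.0 ± 0.38), AT5G27493 (-0.87 ± 0.12), AT4G32620 (-0.85 ± 0.18) and LACS4, a long-chain acyl-CoA synthetase (-0.83 ± 0.19; SD, n = 2), of which AT5G27493 and AT4G32620 turned above 0 with normexp signals.

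No gene flank passed limma at either sign: 0 above and 0 below 0, with 474 above and 118 below at an unadjusted p under 0.05 and a smallest adjusted p of 0.158. Of the 474, 306 lay in the raised stretches. The 0 depends on the processing: normexp signals gave 353 above and 1 below, removal of the GC trend 138 and 6, the deposited values 105 and 6, and robust eBayes with a trend 103 and 3. A wider gene span, which also changed the probes and genes measured, gave 174 and 5, while loess and the fits with 4 arrays as units called 0.

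**Figure D3:**
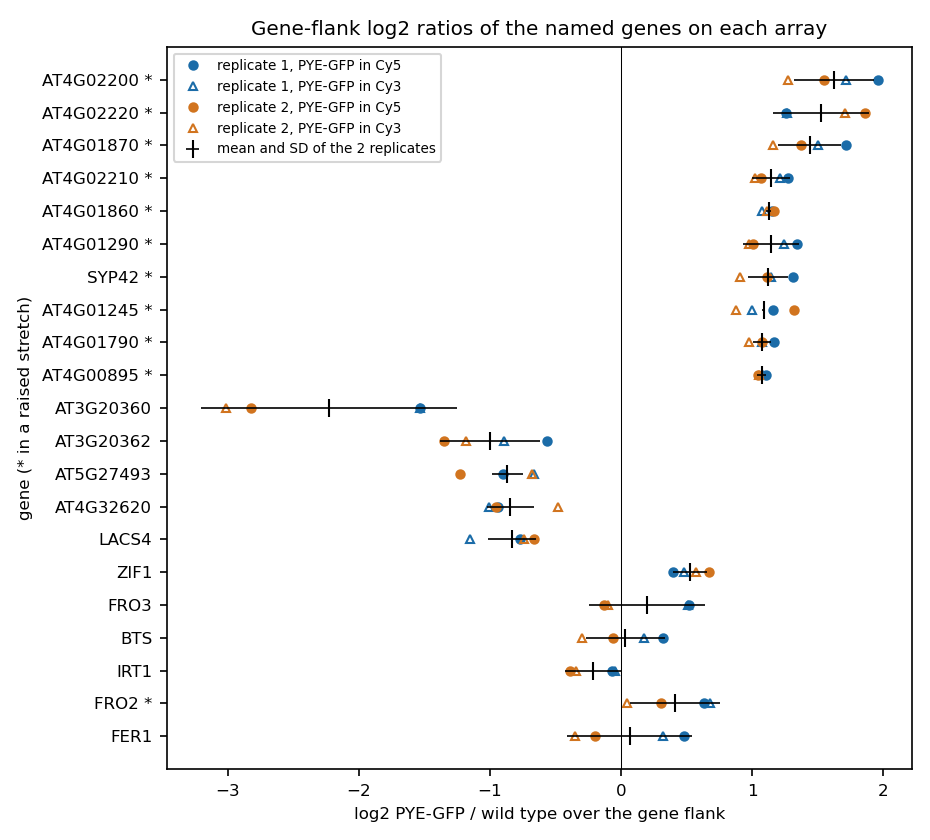
Log2 ratio of PYE-GFP to wild type over the flanks of the named genes (horizontal axis; genes on the vertical axis) on each of the 4 arrays, with the mean and SD of the 2 replicates. ZIF1 lay above 0 on 4 arrays, with a mean of 0.53, and FRO3 had 0.51 in replicate 1 and -0.12 in replicate 2.

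Iron genes as groups were compared with the other genes by camera. The targets for which the study is known, ZIF1 and FRO3 with a value out of 3 members, had a median of 0.36, against 0.01 over all genes, and an adjusted p of 0.328 in limma's camera. This list was chosen in the study on these lines, so it is not independent evidence. Genes of the vacuole and iron storage had a median of 0.10, genes of plastids and mitochondria 0.08, the regulators of iron deficiency 0.07 and uptake genes at the root surface 0.02, where camera's direction was downward. Chelation and long-distance transport genes had -0.18 and zinc and copper genes -0.05. The background lists stood at 0.00 for genes highly transcribed in roots and -0.06 for seed storage genes, with means of 0.05 and -0.05, and for the highly transcribed genes the median lay just below 0 while the mean and camera pointed up. Of the bHLH Ib factors, bHLH101 alone had a value, 0.05, so the list was not tested. No list passed: camera called 0 of the 9 tested, with 1 at an unadjusted p under 0.05, and 0 with an estimated correlation. No list member passed limma, over all genes or adjusted over the list alone.

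Whether the 14 regions held the E-box bound by bHLH proteins was tested at their peaks. CACGTG, the G-box form, lay within 250 bp in 2 of 14 regions (14.3%) and in 2 of 140 control probes (1.43%), an odds ratio of 11.5 (Fisher's exact test, two-sided, p = 0.0416, adjusted 0.208 over 5 motifs). CATGTG or CACATG lay in 1 of 14 regions and 5 of 140 controls, and CANNTG in 6 of 14 and 57 of 140 (adjusted exact p of 1 for each). The scrambled words GTGCAC and GACGTC lay in 0 regions and 0 controls. Within 100 bp CACGTG was in 0 of 14 regions. Most of the sequence between probes was not searched.

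How far the replicates shared these values was asked across windows, which are not independent. Replicate 1 and replicate 2 correlated at -0.119 (Pearson) and -0.148 (Spearman) over all windows, 0.117 inside the raised stretches of chromosomes 1 and 4 and -0.172 outside them. Over gene flanks the correlation was 0.003. The log2 ratio of replicate 1 correlated at 0.374 with the GC content of probes and that of replicate 2 at -0.071, and with the GC trend removed the windows correlated at -0.082. The signals themselves correlated between replicates at 0.921 for PYE-GFP and 0.964 for wild type. PYE-GFP and wild-type signals correlated at 0.969 within replicate 1 and 0.958 within replicate 2. The correlation of signals between replicates is therefore no measure of shared enrichment.

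**Figure D4:**
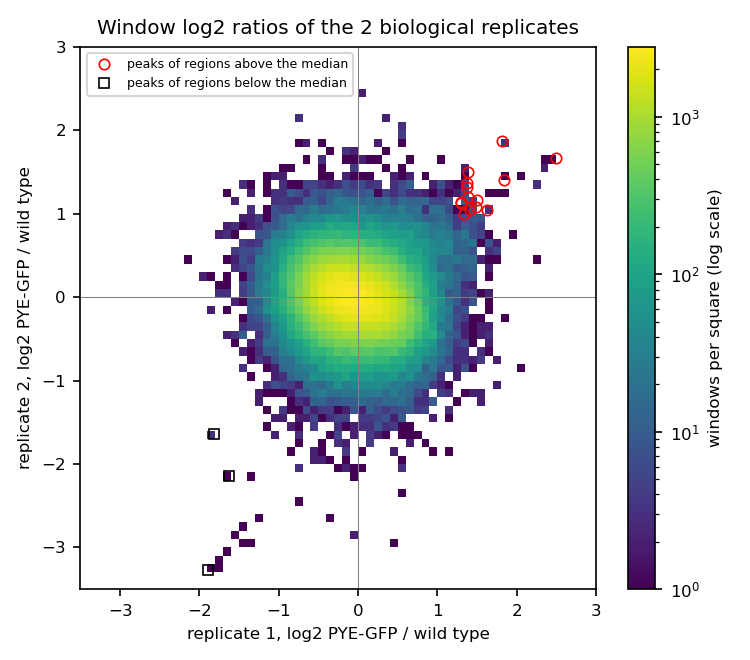
Window log2 ratios of PYE-GFP to wild type in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with the number of windows per square in colour on a log scale and the peaks of regions as circles and squares. Over all windows the correlation was -0.119, and the 14 peaks above the median reached 2.50 in replicate 1.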

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

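No test in this part was chosen after the result was seen. Of 45 values compared over the 4 arrays, 1 had an array far from the others. Chance would give about 1 in 20 for 4 independent arrays, but these are dye-swapped pairs of 2 replicates, so that rate does not apply here. The flank of AT4G32620 was -0.48 on the array of replicate 2 with PYE-GFP in Cy3 and between -1.0 and -0.94 on the other 3 arrays, a gap of 0.878 of the range. Its value rests on 2 probes, and with the narrower gene span it was 0.59. No biological explanation was tested.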

How the results depend on the processing

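The fits with the running median removed, without the raised stretches, with the size rule lowered after the running median, and with the replicate as a random block were chosen after the data were seen, as were the alternatives for the stretch medians and, for the correlation of replicates, those of signals and windows. Main counts are 98 windows above and 39 below 0 by limma, 0 and 0 gene flanks, 66 and 13 windows and 14 and 3 regions by the size rule. In each pair below, the count above comes first. Where no reason is given, the cause was not tested.

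For limma's windows, normexp signals gave 1428 and 8, loess 177 and 25, PYE-GFP in Cy5 only 151 above, PYE-GFP in Cy3 only 21 and 23, windows of 250 bp 35 above, windows of 1000 bp 353 above and robust eBayes with a trend 25 below. Removing the running median gave 13 above, removing the GC trend too 9 and 18, and leaving out the stretches, which held 69 of the 98, 13 and 25. The fits of 4 arrays gave 0 and 0, both with a dye term and with the replicate as a random block and no dye term; at an unadjusted p under 0.05 they had 13475 above and 17284 below, and 5053 and 4756. At an unadjusted p under 0.001 there were 492 and 160. With the sign of replicate 2 turned limma called 8 and 9. The planned fit with both a dye term and the replicate block could not be estimated and was not run. Leaving out a replicate leaves limma no residual degree of freedom, so it gave no count of calls.

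For gene flanks, normexp signals gave 353 and 1, the filter on dim probes 3 and 1, removal of the GC trend 138 and 6, PYE-GFP in Cy5 only 65 and 3, in Cy3 only 3 and 1, the authors' deposited values 105 and 6, the narrower span 8 and 1, the wider span 174 and 5, robust eBayes with a trend 103 and 3, removal of the running median 1 below, and an unadjusted p under 0.001 37 and 1. Loess, both corrections together, leaving out the stretches and the fits of 4 arrays gave 0 and 0.

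For windows by the size rule, normexp signals gave 411 and 0, loess 179 and 20, removal of the GC trend 124 and 22, the filter on dim probes 24 below, removal of the running median 17 above, both corrections 28 and 28, leaving out the stretches 15 above, windows of 250 bp 25 above, windows of 1000 bp 225 above, 2 robust SD 651 and 123, 4 robust SD 12 and 5, and 2 robust SD after the running median 135 and 141. Leaving out a replicate, which drops the demand on it, gave 502 to 1169 above and 185 to 1430 below. For regions, normexp signals gave 98 and 0, loess 42 above, removal of the GC trend 31 and 5, removal of the running median 2 above, both corrections 4 and 6, leaving out the stretches 2 above, windows of 250 bp 7 above, windows of 1000 bp 46 above, 2 robust SD 154 and 31, 4 robust SD 2 above, and 2 robust SD after the running median 35 and 38. Leaving out a replicate gave 133 to 315 above and 52 to 423 below.

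The median of the chromosome 4 stretch, 0.71 over both replicates, was 0.40 with normexp signals and 0.64 with loess, and that of the chromosome 1 stretch, 0.41, was 0.22 and 0.37. Without a replicate they ranged from 0.69 to 0.74 and from 0.40 to 0.42. The correlation of replicates over windows, -0.119, was 0.003 over gene flanks, -0.172 without the stretches, -0.030 with loess and -0.048 with PYE-GFP in Cy5 only. The odds ratio of CACGTG, 11.5, was 0 within 100 bp, 7.61 within 500 bp and 2.59 for the 35 regions at 2 robust SD after the running median (adjusted exact p over all settings from 0.0655 to 1). That of CANNTG, 1.09, was 0.682 within 100 bp, 1.8 within 500 bp (adjusted exact p 0.673) and 0.939 for those 35 regions. No gene list passed camera under any alternative.

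Among named flanks, none of which passed limma, AT5G27493 turned to 0.075, IRT1 to 0.092 and AT4G32620 to 0.095 with normexp signals. With the narrower span AT4G32620 gave 0.59, BTS -0.040, IRT1 0.086 and FER1 -0.084. PYE-GFP in Cy3 only gave BTS -0.063 and FER1 -0.014. FER1 was -0.024 with loess, -0.016 with the GC trend removed and -0.018 with both corrections. FRO2 was -0.045 after the running median was removed. Without a replicate, FRO3 ranged from -0.12 to 0.51, BTS from -0.18 to 0.24 and FER1 from -0.27 to 0.40, the lower value being that of replicate 2. Of the other values for named flanks, 239 kept sign and side of the threshold and 89 passed it, and for region peaks 150 moved by less than the SD and 70 by more. ZIF1 stayed above 0 under all alternatives run, from 0.23 to 0.62, with limma's adjusted p from 0.112 to 1. Between 90.9% and 96.1% of probe spots stood well above background in the PYE-GFP channel. Even so, the filter on dim probes gave 3 gene flanks above and 1 below 0, against 0 and 0 without it. No paired analysis was possible because there is 1 group, and PYE-GFP and wild type already share each array.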

Other observations

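The tests of GC content and of single arrays, that of separate sites on chromosome 1, that of an added copy at the highest region, those of the agreement of replicates, and the removal of the running median were chosen after the result was seen. The test of extra copies was changed then too.

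The raised stretches of chromosomes 1 and 4 are broad. The GC trend carried at most 0.0555 of a stretch median, which argues against GC content as the whole cause, and the demand on both replicates gave the same stretches without the GC correction, although replicate 1 alone then ran to 900000 on chromosome 1. Stretches sought on 1 array alone lay at the same chromosome ends, and the lowest median on an array not used to find them was 0.324, which argues against a single array; with normexp signals 1 array had 0.058 on chromosome 1, and the other 3 had 0.21 to 0.28, so the argument is weaker there. Both stretches were found as runs of bins of 100 kb whose GC-corrected medians were above 0.25 in both replicates. Most probes in them were thus above 0.25 by that rule, and a raised lower quartile of windows was partly built in. It therefore gives no independent argument against separate binding sites, which stay open. At the edge on chromosome 4, GC-corrected medians were 0.985 and 0.693 from 980001 to 990000. From 990001 to 1000000 they were -0.265 and 0.198. Past the edge on chromosome 1, from 720001 to 730000, replicate 1 still had 0.379 and replicate 2 had -0.007. No test was made of these edges. The lower quartile in the chromosome 4 stretch was 0.443 in its lower replicate, and with normexp signals 0.262 and 0.124, the latter under the bound of 0.25. In the chromosome 1 stretch it was 0.150 and 0.203, against -0.242 and -0.230 in the rest of the genome. It lay there at least 0.168 (bootstrap SD 0.0329) above the genome's median window, and neither value reached 0.25, the bound used first. With normexp signals it was 0.109 and 0.041 on chromosome 1, against medians of 0.002 and 0.011. Extra copies of these segments in the tagged line may be a source and stay open. The bound set beforehand counted medians inside and outside gene bodies more than 0.25 apart in a replicate against extra copies. Replicate 1 was 0.353 apart on chromosome 4, so the planned test spoke against them. But replicate 1 differed by 0.236 genome-wide, so the test was changed after the values were seen. Beyond the genome's own difference the medians were up to 0.117 apart, which did not decide. The labels list no input DNA that could decide. Altered chromatin over a whole chromosome end was not tested.

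The highest region of chromosome 3 is unlikely to be a coincidence of the replicates: 0 of 100 circular shifts gave a region as high in its lower replicate, 1.67, the highest being 1.47, and the same region was the highest of replicate 1 alone, with 1.50 on the lower array of replicate 2, which argues against a single array. It could be bound DNA or an added copy of a short segment, and these cannot be told apart without input DNA. The mean log2 ratio of the outer probes was 0.756 of that of the middle ones in replicate 1 and 0.856 in replicate 2. Replicate 1 had 3.55 at 17577955 and 3.68 at 17578439, with 1.86 at 17578237 between them. The quotient thus does not measure a fall from 1 peak. The tagged line carries ProPYE:PYE:GFP, and PYE lies in the part of chromosome 3 where genes were not named. The displacement of the numbering was settled in the blocks that hold the region, at -11000 and -11050 bp, but positions were not converted. An overlap with PYE was not checked, although the settled displacement would have allowed it, so it stays open here.

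The replicates shared little outside the stretches. Removing the GC trend left the window correlation at -0.082 (bootstrap SD 0.0445), which speaks against that trend as the whole cause. Dyes of replicate 2 recorded the wrong way round would turn the highest stretch found on replicate 1 alone, that of chromosome 4, but its median in replicate 2 was 0.693. Hybridisation noise is unlikely as the cause, since the lower correlation of dye-swapped arrays was 0.855. Differences between the immunoprecipitations or their amplification were not tested, and no biological explanation was tested.

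ZIF1 may have PYE-GFP signal beside it. With the running median removed, its highest window was 0.94 in replicate 1 and 0.91 in replicate 2. Of 5449 genes with a like number of probes, 3 (0.0551%), ZIF1 itself among them, were as high in the lower replicate. The nearest region, found at 2 robust SD, shares probes with the highest window of ZIF1, so they are not separate signals. It ran from 4430811 to 4431495 on chromosome 5 over SIG4, a plastid sigma factor gene next to ZIF1, at 1.44 and 0.75. But 16 of 100 circular shifts gave as many regions as the 35 found at that rule. Its probe at 4431122, with 3.11 in replicate 1 and 1.73 in replicate 2, lay outside the flank of ZIF1. FRO3 had 1.63 and 0.07, and 37.2% of genes were as high, so its placement could be chance. These are 2 of the 3 targets for which the study is known, and NAS4 was not analysed here. The targets were chosen in the study on these lines, so the rank of ZIF1 is not independent evidence.

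Outside the stretches, 1 bin of 100 kb, at the right end of chromosome 4 from 18500001 to 18600000, also stood above 0.25 in both replicates, at 0.54 and 0.37 over 55 probes.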
